A study of Mus musculus with 12 samples.

How the data were processed

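Polyadenylated RNA was sequenced from mouse bone marrow mesenchymal stromal cells of the C57BL/6 strain, either wild type (WT) or homozygous for a knockout of Prkcb (KO). The cells were kept in monoculture or in co-culture with primary human chronic lymphocytic leukaemia (CLL) cells, over a total of 48 hours, and CLL cells were depleted with magnetic beads against CD19 before RNA extraction. Libraries were made with a directional kit after poly(A) selection. There were 12 libraries in 4 groups of 3: WT monoculture, KO monoculture, WT co-culture and KO co-culture, with replicates numbered 1 to 3 in monoculture and lettered A to C in co-culture. The submitters call the replicates biological without naming what differs between them, so the p-values rest on the spread between these libraries, whether that lies between animals, CLL donors or dishes. That spread was estimated per gene over all 4 groups together and is not that of the groups compared alone. Because co-cultures varied more than monocultures, the shared spread can be too small for co-cultures and too large for monocultures.

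Groups were read from the sample titles, which match the design text. The treatment field of the labels contradicts them: it calls every WT sample a monoculture and every KO sample a co-culture, so for 6 libraries the titles and that field differ.

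The deposited table holds raw read counts per gene symbol, which the authors made without normalization; every value is a whole number. The submitters' processing notes name CASAVA, Trim Galore 0.4, STAR and HTSeq 0.11.0 and the builds mm10 and GRCm38.p5, without saying which step used which build, whether counting used the strand, or how reads shared between genes were handled. Values of close paralogs (Oas1a and Oas1g, Ifit3 and Ifit3b, the Gbp genes) and of genes with many processed copies (Pgk1, Eno1) are less certain for that reason. The table has 51734 rows, of which 27087 had a count in any library. In 26 rows the symbol had been turned into a date, with 2 such names occurring more than once; these rows hold 0.24% of all counts, were kept in the totals and were not named. Gene positions come from a GENCODE annotation of GRCm38 and give the whole gene, exons, introns and untranslated regions included; the counts cannot be assigned to parts of a gene.

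Library totals ranged from 14128826 to 20336447 counts. A count of 0 in a group was given an upper limit of 3 counts over the group's summed total, and folds against such a group are lower bounds computed with that limit. Ratios with 1 to 3 counts in a group carry a 95% counting interval. Intervals and limits cover counting error only, since reads without molecular identifiers are not independent molecules. Levels are CPM, edgeR's counts scaled to a common library size after TMM, as the mean ± SD of 3 libraries.

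Differential expression was tested in R 4.3.3 with edgeR 4.0.16: filterByExpr by group (minimum count 10) left 14373 genes, TMM factors scaled the libraries, and a robust quasi-likelihood fit with 4 group means over the 12 libraries gave a two-sided F-test per gene. Benjamini-Hochberg adjustment was made over the genes tested, with a threshold of 0.05. The 5 comparisons were co-culture against monoculture in each genotype, KO against WT in each culture, and the interaction, which is the co-culture change in KO minus that in WT. Changes are log2 ratios ± standard error (SE).

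A set of 24 gene lists was tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01. The 16 pathway lists were NF-kB targets, cytokines and growth factors, interferon response, extracellular matrix, matrix proteases and inhibitors, adhesion molecules, lysosome and TFEB targets, glycolysis and hypoxia, cell cycle, cholesterol synthesis, ATF4 and unfolded protein response, Notch pathway, Wnt pathway, complement, contractile and TGF-beta targets, and PKC family. The 8 marker lists were B cell, macrophage, T and NK cell, granulocyte and mast cell, endothelial, adipocyte, osteoblast and mesenchymal stroma. All 536 symbols were found in the table. Lists with at least 5 tested members had a set test (21 lists, 105 tests adjusted together). With the correlation estimated per list, 0 of the 105 camera tests passed, against 55 with the preset correlation; fry passed 51 in its directional form, which asks whether a list's genes move on balance one way, and 73 in its mixed form, which asks whether they change in either direction. Neither form of fry compares a list with other genes.

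Named genes followed a rule. It took Prkcb in every library, then in each comparison up to 10 genes with the highest and 10 with the lowest log2 change among those that passed, changed by at least 1 on the log2 scale, had a mean of at least 5 CPM, did not overlap between the groups (not asked for the interaction) and had an assigned symbol. The mean CPM was taken over all 12 libraries, so a named gene can be low in both groups compared. In each list and comparison the rule took up to 4 members with the smallest adjusted p, or up to 2 where none passed. Genes named outside the rule were chosen after their values were seen, also where this is not said beside them. Groups, comparisons, tests, lists, this rule and most alternatives were fixed before the data were examined. Tested sex-linked genes, 5 in number, were left out of the tables of genes.

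Alternatives were DESeq2 1.42.0 size factors inside edgeR, the DESeq2 Wald test, no low-count filter, a replicate block of 3 or 6 levels, only the 6 libraries of a comparison, and leaving out each library in turn. The block of 3 joined monocultures 1, 2 and 3 with co-cultures A, B and C, a pairing the labels do not give. Deviations from the group mean matched the other genotype's library of the same letter best in 5 of 6 co-cultures. For the same number this held in 0 of 6 monocultures, and no such correlation exceeded 0.1. A fit without both co-culture libraries of letter C and one scaled by library size only were added after the data had been seen. The test was tried on simulated data made from these counts, where it recovered 75.8% of changes of 1 on the log2 scale in the WT co-culture comparison, 83.3% in that of KO and 65.2% in the interaction, with 2.4% to 5.75% false calls. Of changes of 0.5 it recovered 51.5%, 65.2% and 24.2% in the same order. The simulation gave each gene the same spread in all groups, whereas the real co-cultures varied more than the monocultures. These shares therefore need not hold for the real data. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.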

Results

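The data are counts of polyadenylated mouse RNA from bone marrow mesenchymal stromal cells, the adherent fibroblast-like cells of marrow that support blood cells in culture. They were grown alone or for 48 hours with human CLL cells, a leukaemia of mature B lymphocytes. The cells were WT or lacked Prkcb, which encodes protein kinase C beta, a kinase activated by calcium and diacylglycerol. Each of the 4 groups had 3 libraries. Total counts were 15031906, 14896553 and 17980498 in WT monocultures 1 to 3 and 18458315, 17212815 and 20336447 in KO monocultures 1 to 3. They were 15005579, 19921523 and 19186085 in WT co-cultures A to C and 14128826, 14483577 and 17157992 in KO co-cultures A to C.

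Prkcb itself (chromosome 7, 122288751 to 122634402) was barely seen in any group. It had 0 counts in all 6 monocultures, which allows up to 0.0626 CPM in WT and 0.0536 CPM in KO. WT co-cultures A, B and C held 0, 2 and 3 counts of it, and KO co-cultures A, B and C held 6, 3 and 1. A difference between the genotypes in Prkcb was not detectable at this depth, so its level does not check the genotype of a library.

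The 12 libraries parted by genotype first. The first principal component held 91.3% of the variance and separated all WT from all KO libraries; the second held 2.78%. Co-cultures varied more than monocultures: the biological coefficient of variation was 0.0358 in WT monoculture, 0.042 in KO monoculture, 0.112 in WT co-culture and 0.16 in KO co-culture. KO co-culture C stood apart, at 45.2 on the second component against 11.2 and -3.8 for KO co-cultures A and B, and its counts differed from theirs with a chi-squared per degree of freedom of 47 and 61, against 15.2 between A and B. WT co-culture B, at 1 on that component, lay nearer the WT monocultures (-12.3 to -9.9) than WT co-cultures A and C (11.2 and 22.9) did.

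**Figure D1:**
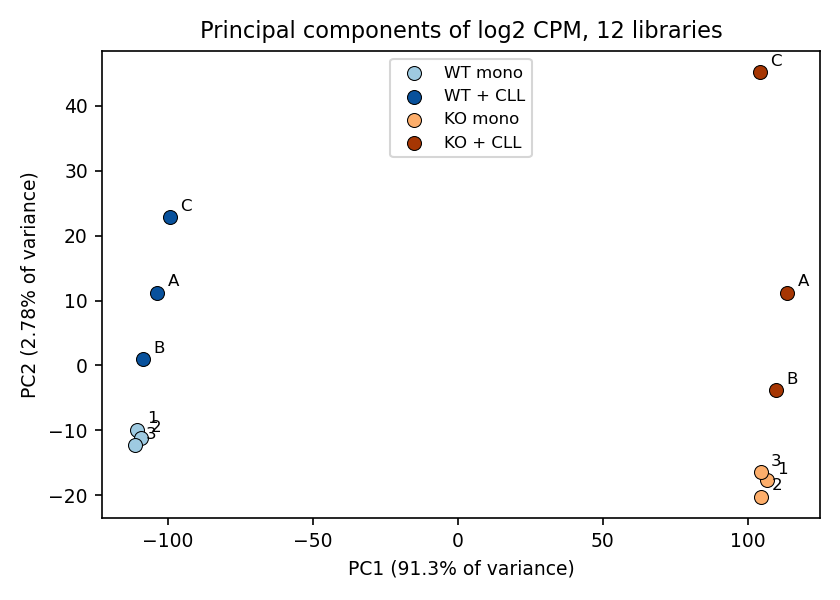
Principal components 1 (x axis, 91.3% of variance) and 2 (y axis, 2.78%) of log2 CPM over the 14373 tested genes, 1 point per library, coloured by group and labelled by replicate. WT and KO libraries lie at opposite ends of the first component, and the co-culture libraries scatter more widely than the monocultures.

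The first comparison asked what contact with CLL cells changes in WT stroma. Interferon-stimulated genes made up the named genes with the highest change. Of 41 tested genes of the interferon response list, 37 were higher in co-culture and 0 lower, with a median log2 change of 1.99. Ifit1 (chromosome 19, 34640871 to 34650009), which binds viral RNA lacking self marks, rose from 26 ± 6.6 to 159 ± 83.3 CPM (log2 2.62 ± 0.48, adjusted p 0.0274). Isg15 (chromosome 4, 156199424 to 156200818), a ubiquitin-like modifier, rose from 27.5 ± 11.2 to 166 ± 69.1 CPM (2.6 ± 0.46, adjusted p 0.0247).

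The 10 named genes with the highest log2 change in WT co-culture were Oas1g (3.11), Ifit3b (3.09), Oas3 (3.06), Zbp1 (3.05), Ifit3 (3.04), Ifi207 (2.87), Irf7 (2.67), Oasl2 (2.67), Iigp1 (2.66) and Ifit1, all known as interferon-induced. Oas1g was 3.85 without WT monoculture 1, and Zbp1 2.32 and Ifi207 2.24 without WT co-culture C; Oas1g and Zbp1 did not pass in those fits. Oas1g was low in WT, with 10 counts over the monocultures (0.217 CPM) and 102 over the co-cultures (1.88 CPM). Irf7 (chromosome 7, 141262706 to 141266481), a transcription factor that amplifies type I interferon, went from 11 ± 3.85 to 69.8 ± 28.4 CPM. The smallest adjusted p values of the interferon response list belonged to Psmb8 (1.54 ± 0.24, adjusted p 0.0126), a subunit of the immunoproteasome, the MHC class I genes H2-K1 (0.75 ± 0.13) and H2-D1 (0.55 ± 0.10), and Ifih1 (1.56 ± 0.25), a sensor of double-stranded RNA. The 4 members that did not pass were Mx1 (2.25), Mx2 (2.18), Gbp2 (1.70) and Gbp4 (0.75), named after their values were seen. Adjusted over the list alone, 40 members were higher. The list passed camera (adjusted p 5.94e-38) and fry (adjusted p 0.00174), with adjusted p = 0.284 with an estimated correlation. Macrophage markers summed to 15.35 CPM in WT co-culture and 12.92 in WT monoculture, and the 11 tested genes of the B cell list to 4.12 and 4.82 CPM.

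**Figure D2:**
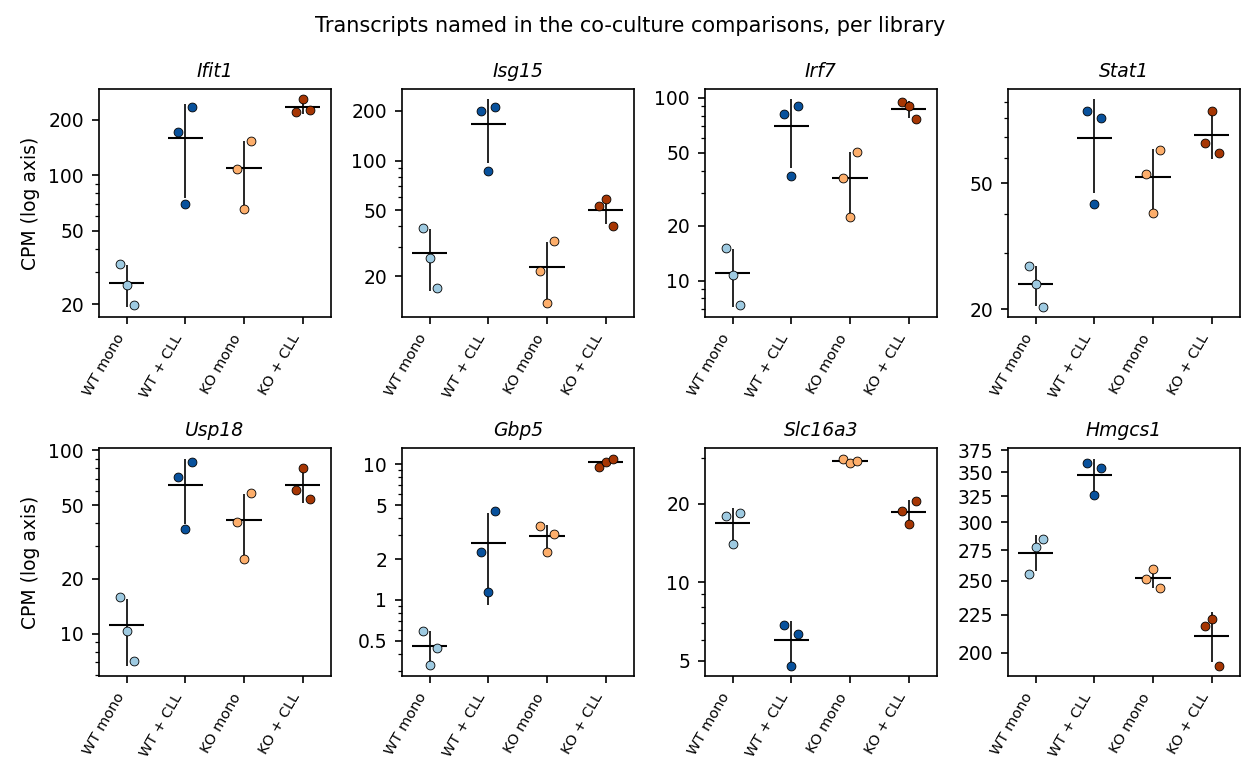
Levels of Ifit1, Isg15, Irf7, Stat1, Usp18, Gbp5, Slc16a3 and Hmgcs1 in CPM (y axis, log scale) in the 4 groups (x axis); points are libraries, lines the mean and bars the SD of 3 libraries. Isg15 averaged 27.5 CPM in WT monoculture and 166 in WT co-culture, against 22.6 and 50.6 in KO.

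Genes of glycolysis and of the response to low oxygen were lower in WT co-culture. The glycolysis and hypoxia list had 8 of 26 members lower and 0 higher (0 higher and 17 lower adjusted over the list alone), with a median of -0.26 (camera adjusted p 1.24e-11, adjusted p = 0.106 with an estimated correlation). Slc16a3 (chromosome 11, 120948480 to 120960868), the lactate exporter MCT4, fell from 16.8 ± 2.4 to 5.99 ± 1.09 CPM (-1.5 ± 0.14, adjusted p 0.000214). Pdk1 (chromosome 2, 71873224 to 71903858), which restrains pyruvate oxidation, fell from 87 ± 1.05 to 51.6 ± 2.61 CPM (-0.76 ± 0.06, adjusted p 7.86e-05). Ldha, which makes lactate, changed by -0.48 ± 0.06, and Pfkl, the liver-type phosphofructokinase, by -0.61 ± 0.08. Cholesterol synthesis genes were higher in WT co-culture, 12 of 22 over all genes tested and 21 adjusted over the list alone, with a median of 0.32 (camera adjusted p 4.26e-14, adjusted p = 0.106 with an estimated correlation). Lss (chromosome 10, 76531588 to 76557138), lanosterol synthase, rose from 147 ± 3.37 to 196 ± 11.8 CPM (0.41 ± 0.06, adjusted p 0.00436). Mvd (0.57 ± 0.09), of the mevalonate pathway, Acat2 (0.59 ± 0.09) and Insig1 (0.29 ± 0.05), a sterol sensor partner, also rose.

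Among NF-kB targets 3 of 28 rose in WT co-culture (4 adjusted over the list alone), namely Vcam1 (0.63 ± 0.13), an adhesion receptor for lymphocytes, Irf1 (0.46 ± 0.10) and Cxcl10 (2.09 ± 0.40), a chemokine that interferons also induce; the list's median was 0.32, or 0.28 with a member at 0 placed at its bound (camera adjusted p 0.00333, adjusted p = 0.531 with an estimated correlation). Of 25 cytokines and growth factors 3 rose, the chemokines Ccl5 (1.57 ± 0.35) and Ccl9 (1.27 ± 0.28) and the growth factor Fgf7 (0.43 ± 0.10), and 5 adjusted over the list alone. The list's median was 0.27 (camera adjusted p 0.0304, adjusted p = 0.406 with an estimated correlation). In the lysosome and TFEB target list Gpnmb (0.88 ± 0.16) and the cholesterol carrier Npc2 (0.38 ± 0.10) rose, 2 of 48 members and 4 adjusted over the list alone, with a median of 0.14 (camera adjusted p 3.45e-06, adjusted p = 0.381 with an estimated correlation).

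Osteoblast markers were lower in WT co-culture, by a median of -0.92 over 8 members (camera adjusted p 0.000364, adjusted p = 0.284 with an estimated correlation). Sp7 (chromosome 15, 102356606 to 102367182), the osterix transcription factor, fell from 118 ± 8.73 to 64.2 ± 20.7 CPM (-0.88 ± 0.20, adjusted p 0.042). It was the 1 member called over all genes, with 7 lower adjusted over the list alone. Ibsp, bone sialoprotein, stood at 2590 ± 451 and 1330 ± 638 CPM (-0.97 ± 0.35, adjusted p 0.178). In the Wnt pathway Wnt5b fell by 0.72 (adjusted p 0.021), 1 of 22 members and 3 adjusted over the list alone. The median stood at -0.28 (camera adjusted p 0.00268, adjusted p = 0.284 with an estimated correlation). The matrix crosslinker Loxl2 (-0.57 ± 0.09) and the collagen Col12a1 (-0.63 ± 0.15) fell among 35 extracellular matrix genes (3 higher and 2 lower adjusted over the list alone, median -0.09, camera adjusted p 0.0669). Among 30 adhesion molecules Vcam1 and the integrin Itgb7 (1.39 ± 0.31) rose and Itgav fell (-0.31 ± 0.08), with 6 higher and 6 lower adjusted over the list alone; the median of -0.02 became 0.01 with library size as the only scaling (camera adjusted p 0.536). Of the markers, Cd14 rose among 15 macrophage genes (0.68 ± 0.17, median 0.13, camera adjusted p 0.586) and Nt5e fell among 10 mesenchymal stroma genes (-0.60 ± 0.11, median 0.14, camera adjusted p 0.22).

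No member was called by edgeR in 11 further lists with 144 tested members, of which 22 had an unadjusted p under 0.05 and 4 passed the DESeq2 Wald test. Their camera adjusted p values were 0.85 for matrix proteases and inhibitors, 0.0797 for cell cycle, 0.111 for ATF4 and unfolded protein response, 0.585 for the Notch pathway, 0.53 for complement, 0.246 for contractile and TGF-beta targets, 0.959 for the PKC family, 0.663 for the B cell list and 0.494 for adipocyte markers. The B cell list's median of 0.33 and mean of -0.01 differed in sign, and its median was 0 in the DESeq2 Wald fit. The T and NK cell list (2 tested members, 1 lower adjusted over the list alone) and the endothelial list (1) were too short for a set test, and the granulocyte and mast cell list had 0 tested members. Outside the lists, the named genes with the lowest change were Slc8a3 (-1.68), a sodium-calcium exchanger, Celsr2 (-1.61), Prex1 (-1.54), Srgap1 (-1.37), Clec4e (-1.32), Gpr141 (-1.28), Cmya5 (-1.18), Dpep2 (-1.16) and Kcnma1 (-1.13). Some of these were low in WT and met the minimum level through the KO libraries. Celsr2 went from 1.07 to 0.354 CPM (51 to 19 counts), Clec4e from 1.51 to 0.591 and Dpep2 from 2.42 to 1.11.

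In all, 527 genes (3.67% of those tested) differed between co-culture and monoculture in WT, 336 higher and 191 lower, of which 102 and 35 by at least 2-fold. The count fell to 89, 70 and 14 without WT monoculture 1, 2 and 3, to 114 and 156 without WT co-culture A and C, and rose to 1314 without WT co-culture B; in the same order the interferon response list held 7, 0, 0, 1, 5 and 40 called members with a median between 1.75 and 2.27, and cholesterol synthesis 3, 3, 1, 4, 4 and 16. Glycolysis and hypoxia had 5 calls without WT monoculture 3, and the lists with 1 to 3 calls had 0 without it, 0 or 1 without WT monoculture 1 or 2 or WT co-culture A, 0 to 2 without WT co-culture C and 2 to 13 without WT co-culture B; with only the 6 libraries of the comparison 244 genes were called, 2 of them in the interferon response list.

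The next comparison asked the same of KO stroma. On co-culture with CLL cells 3 of 13 complement genes rose there, while 9 of 26 genes of glycolysis and hypoxia, 3 of 30 of the cell cycle and 4 of 25 of the ATF4 and unfolded protein response fell (adjusted p = 0.284, 0.106, 0.406 and 0.381 with an estimated correlation). C4b (chromosome 17, 34728380 to 34743882), a complement component, rose from 6.88 ± 0.204 to 17.2 ± 4.03 CPM (log2 1.32 ± 0.25, adjusted p 0.0195). P4ha1 (chromosome 10, 59323296 to 59373304), a collagen prolyl hydroxylase induced in low oxygen, fell by 1.19 (SE 0.11, adjusted p 0.000164). Interferon-stimulated genes had positive changes in all 41 members, and 1 of them passed.

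Of 13 complement genes 3 rose in KO co-culture, C4b, the C1 inhibitor Serping1 (47.1 ± 1.94 to 75.1 ± 17.3 CPM, 0.67 ± 0.13) and Cfb (2.35 ± 0.47), and 5 adjusted over the list alone. The median change was 0.61 (camera adjusted p 1.72e-05, adjusted p = 0.284 with an estimated correlation). In the interferon response list Gbp5 (chromosome 3, 142493978 to 142522344), a guanylate-binding protein, was the member that passed (1.80 ± 0.33, adjusted p 0.0195), with 6 higher adjusted over the list alone and a median of 0.73. That list passed camera (adjusted p 1.7e-13, adjusted p = 0.406 with an estimated correlation) and not fry (adjusted p 0.0716). Ifit1 stood at 109 ± 44.2 CPM in KO monoculture and 235 ± 20.4 in KO co-culture (1.10 ± 0.44, adjusted p 0.2). In the same libraries the macrophage markers summed to 3176 CPM in monoculture and 4396 in co-culture: of 15 tested, Lyz2 (0.81 ± 0.15), lysozyme, Msr1 (0.60 ± 0.11), a scavenger receptor, and Clec4d (0.45 ± 0.10) rose, 11 adjusted over the list alone. The median over the list was 0.32 (camera adjusted p 0.0139, adjusted p = 0.351 with an estimated correlation). The lysosomal enzymes Ctsd (0.46 ± 0.08), Gusb (0.22 ± 0.05) and Ctsb (0.40 ± 0.10) rose, 3 of 48 lysosome and TFEB targets and 10 adjusted over the list alone. The list median was 0.08 (camera adjusted p 0.00776, adjusted p = 0.531 with an estimated correlation).

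Within glycolysis and hypoxia 9 of 26 members fell in KO co-culture (17 adjusted over the list alone, median -0.29, camera adjusted p 3.07e-10, adjusted p = 0.106 with an estimated correlation). Besides P4ha1 they included Pdk1 (80.6 ± 2.85 to 53.5 ± 3.44 CPM, -0.59 ± 0.06), Pfkl (-0.56 ± 0.09), Pgk1 (-0.55 ± 0.09) and Slc16a3 (29.3 ± 0.567 to 18.7 ± 1.94 CPM, -0.65 ± 0.12). DNA replication genes Mcm2 (-0.39 ± 0.08), Mcm4 (-0.37 ± 0.09) and Rrm2 (-0.51 ± 0.12) fell, 3 of 30 cell cycle genes and 13 adjusted over the list alone. This list's median was -0.30 (camera adjusted p 1.1e-09, adjusted p = 0.406 with an estimated correlation), and it did not pass fry (adjusted p 0.0632). Of 25 ATF4 and unfolded protein response genes 4 fell, the pseudokinase Trib3 (16.8 ± 1.27 to 5.96 ± 1.98 CPM, -1.5 ± 0.22), Atf5 (-0.57 ± 0.09), the alanyl-tRNA synthetase Aars (-0.47 ± 0.08) and Mthfd2 (-0.58 ± 0.13); adjusted over the list alone 1 was higher and 10 lower. Their median stood at -0.22 (camera adjusted p 9.75e-05, adjusted p = 0.381 with an estimated correlation). Of 22 cholesterol synthesis genes Stard4 (-0.32 ± 0.07), Sc5d (-0.27 ± 0.07) and Hmgcr (-0.22 ± 0.05) fell, 5 adjusted over the list alone. The members' median was -0.03 (camera adjusted p 0.206).

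Matrix genes went both ways in KO co-culture. The laminin Lama4 (chromosome 10, 38965515 to 39110188) rose from 60.6 ± 3.1 to 138 ± 41.1 CPM (1.19 ± 0.17), the collagen Col3a1 by 0.43, Nid1 by 0.33 and Loxl3 by 0.50, while Loxl2 fell by 0.50, so 4 of 35 matrix genes were higher and 1 lower (8 and 5 adjusted over the list alone, median 0.03, camera adjusted p 0.474). Of 19 matrix proteases and inhibitors Adamts4 (0.57 ± 0.10) and Plat (0.87 ± 0.17) rose and Adamts1 (-0.57 ± 0.07) fell (6 higher and 3 lower adjusted over the list alone, median 0.15, camera adjusted p 0.0497, adjusted p = 0.406 with an estimated correlation). Cxcl2 was the 1 NF-kB target that passed (-0.51 ± 0.12), although the median of the 28 was 0.47 and 10 were higher and 2 lower adjusted over the list alone (camera adjusted p 9.01e-05, adjusted p = 0.427 with an estimated correlation). Single members passed in 4 further lists: the growth factor Bmp4 (-0.57 ± 0.08, list median 0.08, camera adjusted p 0.983), Sdc2 among adhesion molecules (-0.34 ± 0.07, median -0.02, camera adjusted p 0.247), Prkcd in the PKC family (0.36 ± 0.09, median 0.03, or 0 with library size as the only scaling, camera adjusted p 0.983) and the MHC class II chaperone Cd74 in the B cell list (-0.68 ± 0.09, median 0.24, camera adjusted p 0.409). Adjusted over those lists alone, 1 cytokine or growth factor was lower, 3 adhesion molecules were higher and 7 lower, 2 of the PKC family were higher and 2 lower, and 2 B cell list genes were higher and 1 lower.

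In 8 lists with 77 tested members edgeR called none in KO co-culture, 23 had an unadjusted p under 0.05 and 12 passed the DESeq2 Wald test. Camera adjusted p values were 0.417 for the Notch pathway, 0.983 for the Wnt pathway (median 0.03, or 0 with library size as the only scaling), 0.657 for osteoblast, 0.387 for adipocyte and 0.417 for mesenchymal stroma markers. Contractile and TGF-beta targets reached 0.037 (median -0.16, adjusted p = 0.376 with an estimated correlation), with 1 higher and 5 lower adjusted over the list alone, against 5 higher and 2 lower mesenchymal stroma markers, 1 lower Wnt pathway gene and 0 in the other lists. The named genes with the highest change outside the lists were Tspan11 (2.33 ± 0.244 to 26.1 ± 23.9 CPM, 3.49 ± 0.71, or 2.42 ± 0.43 without KO co-culture C, and not passing without KO monoculture 1, 2 or 3 or KO co-culture A), Nt5dc2 (1.19), Siglec1 (1.17), a lectin of macrophages that interferon induces, Ifi47 (1.14), Gda (1.06), Abcd2 (1.04) and Fndc1 (1.02). Those with the lowest were Ptprq (-1.83), Vldlr (-1.78), H2-Aa (-1.52), Foxq1 (-1.51), H2-Eb1 (-1.32), Stbd1 (-1.31), Unc13c (-1.28) and Slc22a23 (-1.16).

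In all, 365 genes (2.54% of those tested) differed between co-culture and monoculture in KO, 186 higher and 179 lower, of which 23 and 34 by at least 2-fold; 26 higher and 18 lower genes were shared with the WT comparison, against 4.35 and 2.38 for independent sets, and 3 (Cav1, Tnfrsf21 and Fzd5) went opposite ways. The count fell to 37, 31 and 17 without KO monoculture 1, 2 and 3, was 53, 1762 and 353 without KO co-culture A, B and C, and 736 without both co-cultures of letter C. Without KO monoculture 1, 2 or 3 or KO co-culture A, 0 genes of the complement, macrophage, cell cycle, lysosome and interferon response lists passed in edgeR, 3, 1, 0 and 1 of the ATF4 list and 5, 5, 2 and 5 of the glycolysis and hypoxia list; without KO co-culture B these 7 lists held 5, 7, 23, 11, 1, 8 and 11 calls, and without KO co-culture C 3, 7, 1, 2, 1, 5 and 13. The other lists with 1 to 5 calls held 0 or 1 without any KO monoculture or KO co-culture A, 0 to 5 without KO co-culture C and 1 to 12 without KO co-culture B.

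The interaction asked whether the response to CLL cells depends on Prkcb. It passed for 12 genes (0.0835% of those tested), 7 with a more positive change in KO and 5 with a more negative one. Fzd5 (chromosome 1, 64730558 to 64737751), a Wnt receptor, fell by 0.60 in WT co-culture and rose by 0.33 in KO (interaction 0.93 ± 0.11, adjusted p 0.00513). Foxq1 (chromosome 13, 31556134 to 31560976), a forkhead transcription factor, changed by -0.15 in WT and fell by 1.51 in KO (interaction -1.37 ± 0.18, adjusted p 0.0132). Hmgcs1 (chromosome 13, 119690379 to 119708260), an enzyme of the mevalonate pathway, stood at 273 ± 15.3 CPM in WT monoculture, 347 ± 18.1 in WT co-culture, 252 ± 7.4 in KO monoculture and 211 ± 16.2 in KO co-culture (interaction -0.60 ± 0.10, adjusted p 0.0355).

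Cholesterol synthesis had the smallest camera p among the lists: 2 of 22 members passed, Hmgcs1 and Stard4, both negative, 15 were negative adjusted over the list alone, and the median interaction was -0.40 (camera adjusted p 2.55e-15, adjusted p = 0.106 with an estimated correlation). The interferon response list had a median interaction of -1.10 with 0 of 41 members positive (camera adjusted p 1.1e-13, adjusted p = 0.406 with an estimated correlation). None of its members passed in edgeR on its own, 22 had an unadjusted p under 0.05 and 2 passed the DESeq2 Wald test. Osteoblast markers had a median interaction of 0.78 with 8 of 8 positive (camera adjusted p 0.00574, adjusted p = 0.381 with an estimated correlation). Of these edgeR called 0, 1 had an unadjusted p under 0.05 and 1 passed the DESeq2 Wald test. As 7 of the 8 were already lower in KO monoculture than in WT, a further fall in KO was harder to see. Their KO median change of -0.01 was -0.37 with a member at 0 placed at its bound. The glycolysis and hypoxia list, with 8 of 26 members lower in WT and 9 in KO (adjusted p = 0.106 in each with an estimated correlation), had a median interaction of -0.02 (camera adjusted p 0.779). Macrophage markers had a median interaction of 0.53 (camera adjusted p 0.116).

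The count of 12 rose to 114 without WT co-culture B, 161 without KO co-culture B and 62 without KO co-culture C, and fell to 6 and 3 without WT and KO co-culture A, to 3 and 2 without WT monoculture 1 and 3, 7 without WT monoculture 2 and 2 without KO monoculture 1, 2 or 3. A replicate block of 3 gave 10 genes, of which 6 were among the 12. Without WT monoculture 1, 2 or 3, KO monoculture 1, 2 or 3, co-culture A of either genotype or WT co-culture C, 0 cholesterol synthesis genes passed, against 10 without WT co-culture B and 6 and 5 without KO co-culture B and C; its median lay between -0.45 and -0.35 throughout.

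**Figure D3:**
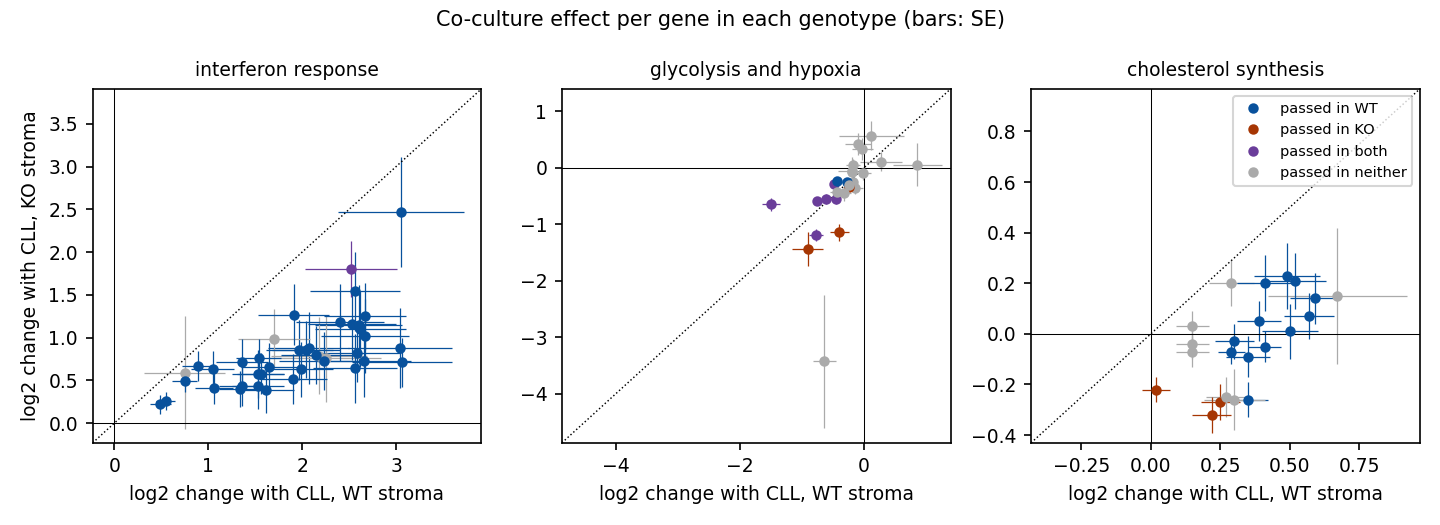
Log2 change from monoculture to co-culture in WT (x axis) and KO (y axis) for each tested gene of the interferon response, glycolysis and hypoxia, and cholesterol synthesis lists; bars are SE, colours mark in which genotype a gene passed, and the dotted line marks equal changes. Interferon genes have a median of 1.99 in WT and 0.73 in KO, and cholesterol genes 0.32 and -0.03.

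KO and WT monocultures were compared to ask what the loss of Prkcb changes in stroma grown alone. The cultures differed in most genes and in the kinds of cell transcripts they held. Transcripts of macrophages were high in KO and low in WT: Lyz2 (chromosome 10, 117277331 to 117282321) stood at 1.91 ± 0.503 CPM in WT and 1140 ± 130 in KO, and Csf1r (chromosome 18, 61100598 to 61132149), the receptor for the macrophage growth factor, at 1.38 ± 0.456 and 373 ± 16.3 (log2 8.10 ± 0.15, adjusted p 8.07e-15). Of 8 osteoblast markers 7 were lower in KO (adjusted p = 0.351 with an estimated correlation): Ibsp (chromosome 5, 104299171 to 104311469) stood at 2590 ± 451 and 1.83 ± 0.592 CPM (-10.47 ± 0.55, adjusted p 1.39e-07), and Alpl (chromosome 4, 137741733 to 137796384), the alkaline phosphatase of mineralising cells, at 866 ± 44.7 and 2.75 ± 0.356.

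All 15 tested macrophage markers were higher in KO monoculture, by a median of 8.50 (camera adjusted p 9.26e-08, adjusted p = 0.106 with an estimated correlation), led by Itgam (9.59 ± 0.16), Mpeg1 (9.38 ± 0.17), Csf1r and Clec4d (9.13 ± 0.23). No other list holds any of these 15. In both comparisons of the genotypes, the counts adjusted over the list alone equal those over all genes unless given. All 11 tested genes of the 30 in the B cell list were higher too, by a median of 8.28 (camera adjusted p 3.14e-06, adjusted p = 0.106 with an estimated correlation). Of these, Cd74 (6.98 ± 0.13), Laptm5 (8.28 ± 0.16), Cd53 (7.49 ± 0.19) and Coro1a (7.84 ± 0.24) are genes that macrophages also express. The 11 summed to 4.82 CPM in WT monoculture, so the low-count filter kept most of them through the KO libraries, which helped to set this count. In the DESeq2 Wald fit, which kept every row with a count, 12 members of the B cell list were higher and 1 lower, and 14 macrophage markers were higher and 0 lower. The granulocyte and mast cell list had 0 tested members, and of 2 tested T and NK cell genes Zap70 was lower in KO (-3.83 ± 0.54). Kdr, the 1 tested endothelial gene, was lower (-2.08 ± 0.57, or -2.92 without KO monoculture 3).

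**Figure D4:**
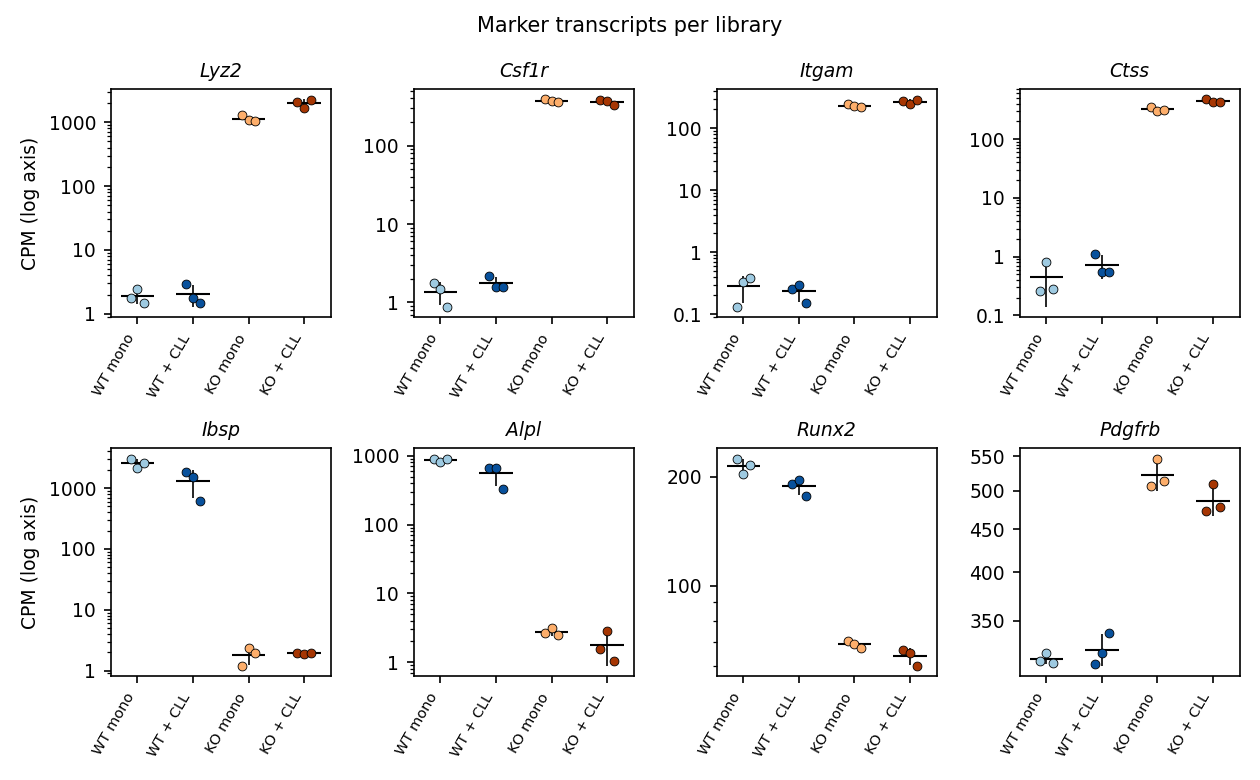
Levels of the macrophage genes Lyz2, Csf1r, Itgam and Ctss, the osteoblast genes Ibsp, Alpl and Runx2 and the stromal gene Pdgfrb in CPM (y axis, log scale) in the 4 groups (x axis); points are libraries, lines the mean and bars the SD of 3 libraries. Csf1r averaged 1.38 CPM in WT and 373 in KO monoculture, Ibsp 2590 and 1.83, and Pdgfrb 315 and 522.

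Osteoblast markers were lower in KO for 7 of 8 members, by a median of -5.70, or -4.25 with members at 0 placed at their bound (camera adjusted p 0.00267, adjusted p = 0.351 with an estimated correlation). Sp7 stood at 118 ± 8.73 CPM in WT and 0.257 ± 0.0947 in KO, and Runx2, the transcription factor upstream of Sp7, at 215 ± 9.95 and 68.9 ± 1.57 (-1.64 ± 0.06). Mesenchymal stroma markers did not follow them: 8 of 10 were higher and 1 lower in KO (median 0.87, camera adjusted p 0.0235, adjusted p = 0.284 with an estimated correlation), with Pdgfrb at 315 ± 4.37 and 522 ± 21.4 CPM, Prrx1 higher by 1.25 and Eng, endoglin, lower by 3.08 on the log2 scale, at 100 ± 2.2 and 11.8 ± 1.93 CPM. Among 5 adipocyte genes 3 were higher and 1 lower, with Lpl, lipoprotein lipase, at 5.67 ± 0.541 and 387 ± 40.3 CPM. The median over the list was 1.23 (camera adjusted p 0.267).

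In the Wnt pathway 17 of 22 members were lower in KO monoculture and 3 higher. The list median was -3.38 (camera adjusted p 0.00119, adjusted p = 0.284 with an estimated correlation). Wnt10b (-8.05 ± 0.19), Wnt5a (-3.61 ± 0.11) and the feedback inhibitor Axin2 (-4.84 ± 0.19) were lower and the receptor Lgr5 higher (7.06 ± 0.18). Complement genes were higher for 12 of 13 (median 3.99, or 3.71 with members at 0 at their bound, camera adjusted p 9.06e-05, adjusted p = 0.319 with an estimated correlation), among them Serping1 (8.73 ± 0.29) and C2 (3.99 ± 0.24). Of 10 Notch pathway genes 7 were higher and 0 lower, such as Notch4 (6.01 ± 0.32) and Notch1 (1.95 ± 0.11), and 1 was lower without WT monoculture 2 or any KO monoculture. The list's median was 1.10 (camera adjusted p 0.0212, adjusted p = 0.284 with an estimated correlation).

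Several metabolic lists were lower in KO monoculture. Cholesterol synthesis had 18 of 22 genes lower and 0 higher (median -0.71, camera adjusted p 3.41e-05, adjusted p = 0.351 with an estimated correlation), with Dhcr24 at 164 ± 1.99 CPM in WT and 37 ± 0.555 in KO and Cyp51 at 406 ± 10.3 and 143 ± 2.64. ATF4 and unfolded protein response genes were lower for 19 of 25 and higher for 5 (median -0.75, camera adjusted p 0.002, adjusted p = 0.427 with an estimated correlation), with Shmt2 (-1.95 ± 0.08), Slc7a5 (-2.41 ± 0.11) and Aars (-1.37 ± 0.08). Glycolysis and hypoxia genes were lower for 15 of 26 and higher for 5, with Ldha lower (-1.62 ± 0.06) and Aldoc higher (4.46 ± 0.24). The median stood at -0.63 (camera adjusted p 0.0212, adjusted p = 0.427 with an estimated correlation). Cell cycle genes were lower for 14 of 30 and higher for 4, or 13 and 4 adjusted over the list alone, with Ccne1 lower by 1.09 and Mcm7 by 0.58 on the log2 scale. The median change was -0.26 (camera adjusted p 0.247).

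Immune and lysosomal lists were higher in KO monoculture, beside macrophage markers summing to 3176 CPM there and 12.92 in WT. Interferon response genes were higher for 31 of 41 and lower for 2 (median 1.49, camera adjusted p 0.000641, adjusted p = 0.652 with an estimated correlation), with H2-D1 (1.5 ± 0.10) and Oas3 (5.79 ± 0.46). NF-kB targets were higher for 14 of 28 and lower for 3, with Cxcl2 (8.09 ± 0.24), Icam1 (7.59 ± 0.28) and Vcam1 at 66.3 ± 4.2 CPM in WT and 590 ± 19.2 in KO. The median over the list was 0.66 (camera adjusted p 0.0212, adjusted p = 0.621 with an estimated correlation). Cytokines and growth factors were higher for 17 of 25 and lower for 5, with Il15 (5.37 ± 0.36) and Csf1 (1.09 ± 0.08). The list median was 0.86 (camera adjusted p 0.0139, adjusted p = 0.381 with an estimated correlation). Lysosome and TFEB targets were higher for 29 of 48 and lower for 7, with Ctsb at 442 ± 10.9 and 1570 ± 23.1 CPM. This list's median was 0.30 (camera adjusted p 0.0167, adjusted p = 0.578 with an estimated correlation).

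Matrix, adhesion and contractile genes went both ways in KO monoculture. Extracellular matrix genes were higher for 13 of 35 and lower for 17, with a median of 0.20 and a mean of -0.24 (camera adjusted p 0.855): Col3a1 (1.34 ± 0.08) and Fbln5 (1.89 ± 0.09) were higher, while Tnc, tenascin C, chosen after its values were seen, stood at 2950 ± 49.8 and 46.3 ± 0.992 CPM. Matrix proteases and inhibitors were higher for 12 of 19 and lower for 5, or 12 and 6 adjusted over the list alone, with Plau (2.50 ± 0.09) and Mmp9 (3.37 ± 0.18) higher and Adamts1 lower (-1.72 ± 0.07). The median stood at 0.71 (camera adjusted p 0.111). Adhesion molecules were higher for 17 of 30 and lower for 11, with Itga4 (4.07 ± 0.10) and L1cam (8.17 ± 0.19) higher and Mcam lower (-7.29 ± 0.19). The median change was 0.71 (camera adjusted p 0.212). Contractile and TGF-beta targets were higher for 5 of 19 and lower for 9, with the smooth muscle actin Actg2 (-9.19 ± 0.16) and Ankrd1 (-7.62 ± 0.14) lower and Tgfbi higher (7.28 ± 0.36). The median over the list was -0.56 (camera adjusted p 0.246). In the PKC family 4 of 9 were higher and 2 lower, or 3 and 1 adjusted over the list alone: Prkch (5.58 ± 0.20), Prkcd (1.42 ± 0.09) and Prkd1 (0.90 ± 0.13) were higher and Prkce lower (-0.40 ± 0.09). Without any 1 of the 6 monocultures, 1 of the family was lower. The list median was 0.17 (camera adjusted p 0.462).

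The named genes with the highest change had 0 to 3 counts over the WT monocultures. Pirb was at least 661-fold higher in KO monoculture, Bst1 532-fold, Cd84 512-fold, Cysltr1 390-fold, H2-Eb1 346-fold, Themis2 327-fold, Raet1d 302-fold, and Tmem26 and Il10ra each 286-fold, and the macrophage metalloelastase Mmp12 had a ratio of 6290 (95% counting interval 1130 to 248000). Those with the lowest included Acan, the cartilage proteoglycan, at a ratio of 6300 in favour of WT (1130 to 249000), Panx3 and Ptprd (each moved by over 1.5 times, without KO monoculture 3 and 2 in that order), and genes with no count in KO: Col22a1 was at least 639-fold lower, Khdrbs3 514-fold, Gabrb3 492-fold, Bmp3 457-fold, Wbscr17 422-fold, Grik2 304-fold and Camk4 288-fold. In all, 10654 genes (74.1% of those tested) differed between KO and WT monocultures, 5414 higher and 5240 lower in KO, of which 2770 and 1867 by at least 2-fold. Genotype, animal and culture could not be separated, since the labels name no independent cultures of a genotype.

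KO and WT co-cultures were compared to ask what the loss of Prkcb changes in stroma that has met CLL cells. Lyz2, Csf1r and Ibsp differed there too: Lyz2 was at 2.04 ± 0.75 CPM in WT and 2000 ± 281 in KO, Csf1r at 1.78 ± 0.352 and 360 ± 28.8, and Ibsp at 1330 ± 638 and 1.93 ± 0.0403. Cholesterol synthesis genes were lower in KO for 21 of 22 (adjusted p = 0.284 with an estimated correlation), and the interferon response list did not pass. Of its 41 members 11 were higher in KO and 3 lower, with a median of 0.32. Isg15, among the 3 lower, stood at 166 ± 69.1 CPM in WT and 50.6 ± 9.23 in KO (log2 -1.72 ± 0.44, adjusted p 0.00669, chosen after its values were seen).

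Macrophage markers were higher in KO co-culture for 15 of 15 (median 8.41, camera adjusted p 3e-08, adjusted p = 0.106 with an estimated correlation) and summed to 4396 CPM in KO and 15.35 in WT. The B cell list was higher for 11 of 11 tested members out of 30 (median 8.87, camera adjusted p 1.72e-06, adjusted p = 0.106 with an estimated correlation), with Cd74 at 1.85 ± 0.541 CPM in WT and 193 ± 12.7 in KO. In the DESeq2 Wald fit, without the low-count filter, 13 of its members were higher and 2 lower. Complement genes were higher for 12 of 13 and lower for 0. The list's median was 5.33, or 4.71 with members at 0 at their bound (camera adjusted p 1.29e-05, adjusted p = 0.284 with an estimated correlation). Osteoblast markers were lower for 6 of 8 and higher for 1, or 7 and 1 adjusted over the list alone (median -2.67, camera adjusted p 0.00915, adjusted p = 0.381 with an estimated correlation), and 0 were higher without WT co-culture A, B or C. Mesenchymal stroma markers were higher for 7 of 10 and lower for 1. Their median was 0.98 (camera adjusted p 0.0398, adjusted p = 0.284 with an estimated correlation). Adipocyte genes were higher for 4 of 5 and lower for 1 (median 1.57, camera adjusted p 0.268), Zap70 (-1.97 ± 0.60) was lower among 2 T and NK cell genes (1 higher and 1 lower adjusted over the list alone), and the endothelial gene Kdr was lower (-2.93 ± 0.58).

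Cholesterol synthesis had a median of -1.10 in KO co-culture against WT co-culture, with 22 lower adjusted over the list alone (camera adjusted p 7.54e-08, adjusted p = 0.284 with an estimated correlation): Lss stood at 196 ± 11.8 CPM in WT and 84.3 ± 3.4 in KO, Cyp51 at 451 ± 16.3 and 140 ± 11.9. ATF4 and unfolded protein response genes were lower for 19 of 25 and higher for 4, with Shmt2 at -2.14 ± 0.08 and Aars at -1.71 ± 0.08. The median change was -1.22 (camera adjusted p 0.000801, adjusted p = 0.406 with an estimated correlation). Glycolysis and hypoxia genes were lower for 18 of 26 and higher for 6, with Ldha at -1.42 ± 0.06. The median over the list was -0.68 (camera adjusted p 0.0167, adjusted p = 0.427 with an estimated correlation). Cell cycle genes were lower for 17 of 30 and higher for 4, with Mcm2 at -0.77 ± 0.08 and Plk1 at -0.89 ± 0.11, and 2 were higher without KO co-culture B or WT co-culture C. The list median was -0.38 (camera adjusted p 0.0197, adjusted p = 0.703 with an estimated correlation). Wnt pathway genes were lower for 17 of 22 and higher for 4, with Wnt10b at -7.78 ± 0.20 and Wnt5b at 3.03 ± 0.13. This list's median was -2.75 (camera adjusted p 0.00281, adjusted p = 0.284 with an estimated correlation). Notch pathway genes were higher for 8 of 10 and lower for 0, with Jag2 at 4.03 ± 0.22. The median stood at 1.29 (camera adjusted p 0.00671, adjusted p = 0.271 with an estimated correlation).

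Among the immune lists in co-culture, NF-kB targets were higher in KO for 17 of 28 and lower for 1 (median 1.01, camera adjusted p 0.0073, adjusted p = 0.566 with an estimated correlation). The lower count was 0 without KO co-culture A or B or WT co-culture C, 2 without WT co-culture B and 4 without KO co-culture C. Cytokines and growth factors were higher for 16 of 25 and lower for 4, with Il15 at 4.77 ± 0.32. The median change was 0.69 (camera adjusted p 0.042, adjusted p = 0.427 with an estimated correlation). Interferon response genes were higher for 11 of 41 and lower for 3, with Oas3 at 3.44 ± 0.34 and Irgm1 at -1.20 ± 0.17, and 7 were lower without WT co-culture B. The median over the list was 0.32 (camera adjusted p 0.242). Lysosome and TFEB targets were higher for 25 of 48 and lower for 12, with Ctsf at 2.89 ± 0.14. The list median was 0.25 (camera adjusted p 0.0616). Matrix proteases and inhibitors were higher for 11 of 19 and lower for 4, with Serpine2 at 3.10 ± 0.12. The list's median was 1.02 (camera adjusted p 0.0385, adjusted p = 0.396 with an estimated correlation).

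Adhesion molecules were higher in KO co-culture for 16 of 30 and lower for 10, or 17 and 10 adjusted over the list alone, with Vcam1 at 102 ± 21.8 CPM in WT and 616 ± 63 in KO. Their median stood at 0.48 (camera adjusted p 0.168). Extracellular matrix genes were higher for 16 of 35 and lower for 17, or 17 and 17 adjusted over the list alone, with a median of 0.16 that was -0.01 in the DESeq2 Wald fit and a mean of -0.09 (camera adjusted p 0.807). Contractile and TGF-beta targets were higher for 4 of 19 and lower for 10. The members' median was -0.91 (camera adjusted p 0.167). In the PKC family 4 of 9 were higher and 4 lower, with Prkch (6.14 ± 0.20) and Prkcd (1.63 ± 0.09) higher; the median was -0.08, the mean 0.85 and the median in the DESeq2 Wald fit 0.32 (camera adjusted p 0.646).

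In all, 10542 genes (73.3% of those tested) differed between KO and WT co-cultures, 5283 higher and 5259 lower in KO, of which 2713 and 1849 by at least 2-fold. Named genes with the highest change were Cthrc1 (at least 516-fold higher), Hand2 (494-fold), Npy (371-fold), Dennd1c (330-fold), Cytip (271-fold), Stap1 (267-fold) and Hoxa11os (266-fold), with ratios of 4380 for Cd300ld (95% counting interval 786 to 173000), 2930 for Pirb (525 to 116000) and 2740 for Cd300lf (491 to 108000). Those with the lowest were Hoxc13 (at least 427-fold lower), Gabrb3 (309-fold), Sdk2 (303-fold), Igfbp5 (261-fold), Peg3 (235-fold), Lhx6 (231-fold), C1qtnf3 (217-fold), Col22a1 (203-fold) and Epha4 (167-fold), with a ratio of 3530 in favour of WT for Acan (634 to 140000). As in monoculture, genotype, animal and culture could not be separated.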

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

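Tests on macrophages, on CLL cells or their RNA, on the loss of Prkcb, on the baseline of the KO cultures and on the animals were chosen after the result was seen. Those on single libraries, on scaling and on other splits were chosen beforehand, except that library size only was added to the scalings afterwards.

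The response to CLL cells differed between the genotypes, by the test of the interaction, in 12 genes. Of these, 6 also passed with a replicate block of 3, whose pairing of numbers with letters is not in the labels. It was more positive in KO for Tnfrsf21, a death receptor (interaction 1.46; -0.82 in WT and 0.64 in KO), Arhgdib, a regulator of Rho GTPases (1.12; -0.99 and 0.14), Nt5e, the ectonucleotidase CD73 (0.93; -0.60 and 0.34), Fzd5 (0.93), Srpx2 (0.85), Lifr, the receptor for leukaemia inhibitory factor (0.83), and Serinc5 (0.70). It was more negative in KO for the caveolin Cav1 (-0.49), Stard4 (-0.54), Adamts1 (-0.58), Hmgcs1 (-0.60) and Foxq1 (-1.37). Arhgdib was low in WT, at 2.38 CPM in monoculture and 1.21 in co-culture, against 112 and 123 in KO, so its interaction rests on low WT levels. Among the lists the median interaction was -0.40 for cholesterol synthesis, -1.10 for interferon response, -0.18 for cell cycle, -0.14 for ATF4 and unfolded protein response, -0.09 for cytokines and growth factors, 0.14 for extracellular matrix, 0.34 for the Wnt pathway, 0.41 for complement and 0.78 for osteoblast markers. All 9 lists passed camera with the preset correlation and none with an estimated one. Directional fry passed cholesterol synthesis (adjusted p 0.000723) and extracellular matrix (adjusted p 0.0365) and none of the others. Members with 0 counts in a group weigh on some of these medians. With them at their bound, the WT co-culture change of complement had a median of 0.26 in place of 0.05, and the KO one of osteoblast markers -0.37 in place of -0.01.

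Of 100 splits of the 12 libraries, 2 gave as many interaction genes as the real count of 12, the real split included, and the highest other count was 73. That split reversed the culture of all 6 KO libraries and exchanged WT co-culture B with WT monoculture 1, so its contrast kept much of the real co-culture changes and added those of the genotypes in place of subtracting them. Splits of culture within genotype also break the change that the genotypes share, so they are no null for an interaction, and chance is not excluded for the 12 genes. Each of the other 4 comparisons has 10 splits, too few for a share under 0.05: the real split was the 1 with the most genes, with 527, 365, 10654 and 10542, and the highest other was 0 in each.

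The first pattern weighed is the macrophage transcripts of the KO libraries. CLL cells left after bead depletion would bring them with co-culture, but the markers already summed to 3176 CPM in KO monoculture, against 4396 in KO co-culture, and changed by a median of 0.32 on adding CLL cells, so the tables argue against CLL cells as their main source. Macrophages among the cells of the KO cultures stay open: 15 of 15 markers were higher in KO monoculture, but they are the pattern itself and do not test its cause, which a sort for CD45-negative cells would. Loss of Prkcb in the stromal cells stays open too: the median difference was 8.41 in co-culture, and with no separate cultures of a genotype in the labels, genotype and cell make-up cannot be told apart. Prkcb had 0 counts in the WT monocultures, where the median difference to KO was already 8.50, so a loss of its RNA could not be seen at this depth.

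The second pattern is the interferon response of WT co-cultures. No single library carried it, since the median with a co-culture library left out was at least 1.75, and macrophages in WT co-culture are argued against by their markers, at 0.349% of the level in KO co-culture. RNA of CLL cells is argued against for the interferon GTPases that human cells lack, whose median change was 1.46 (4 of 5 called higher), and stays open for the other genes. The 11 tested genes of the B cell list had a summed level in WT co-culture minus monoculture of -0.708 CPM. That sum leaves out Pax5 and the other untested members, so it cannot decide on CLL RNA. Pax5 went from 4 to 62 counts, and how far human reads count on mouse genes is unknown. A higher baseline of KO monocultures would explain the smaller rise in KO only for genes that start higher there. The 10 members not called higher in KO monoculture had a negative median interaction of -0.79 (range -1.45 to -0.16, against -1.23 for the other 31). However, 38 of all 41 members had a positive KO change in monoculture, so most of the 10 did too. The split also uses monoculture values that enter the interaction, so the baseline stays open. Whether WT stroma answers CLL cells more strongly than KO stroma stays open, with 0 members passing the interaction alone in edgeR (22 at an unadjusted p under 0.05, 2 by the DESeq2 Wald test), and genotype is confounded with the make-up of the cultures.

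The third pattern is the osteoblast transcripts, lower in KO. Scaling of libraries with different make-up was not tested by the scalings tried, since the TMM factors lay between 0.956 and 1.039 and could move a gene little. Under them the osteoblast median was at most -5.69 in monoculture (-4.25 in the fit used here with members at 0 placed at their bound) and at most -2.66 in co-culture. A scaling error would shift all genes alike, and the mesenchymal stroma median of 0.87 in monoculture argues against it. Macrophages displacing osteoblast RNA would lower all stromal transcripts alike, yet the median log2 difference of osteoblast markers minus that of mesenchymal stroma markers was -6.57 in monoculture. Cultures from different animals stay a possible explanation that these data cannot test, since WT and homozygous KO cells come from different animals by design. In monoculture 4 of 4 sex-linked mouse genes differed between the 2 genotypes, so the sex of the animals may be confounded with genotype. An effect of Prkcb itself was not separable from differences between animals and stays untested.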

How the results depend on the processing

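The fit scaled by library size only and the one without both co-cultures of letter C were chosen after the results were seen. Among the genes named by the rule that had passed, none reversed: of 4295 alternative values for them, 3763 kept their call and 532 lost it, 239 in the WT co-culture comparison, 208 in the KO one, 85 in the interaction and 0 in the comparisons of the genotypes. Named genes that had not passed were left out, so no call could be gained. DESeq2 size factors, library size only and, in the genotype comparisons, every alternative moved the counts by less than 1.5 times. With 1 library left out the count ranged from 14 to 1314 in the WT co-culture comparison, from 17 to 1762 in the KO one, from 2 to 161 in the interaction, from 10094 to 10271 for KO in monoculture and from 10083 to 10692 in co-culture. With only the 6 libraries of a comparison, 244 genes passed in WT and 91 in KO, while KO against WT gave 11413 in monoculture and 9274 in co-culture. Without the low-count filter 812 passed in KO and 120 in the interaction, and with the DESeq2 Wald test 976 and 121; with a replicate block of 3, KO gave 563, and without both letter C libraries KO gave 736 and the interaction 88. The cause of these differences was not tested. The balance of calls turned, however. In KO co-culture 186 higher and 179 lower genes became 152 and 215 with library size only, 7 and 30 without KO monoculture 1 and 402 and 410 without the low-count filter, and lower genes led without KO monoculture 2 or 3 or KO co-culture A too. In WT, 4 higher and 10 lower genes remained without monoculture 3 and 32 and 38 without monoculture 2. The interaction's 7 and 5 became 6 and 7 with library size only, 59 and 61 without the filter, 40 and 74 without WT co-culture B and 74 and 87 without KO co-culture B. The near-even balance of the genotype comparisons turned as well, to 5262 and 5395 in monoculture and 4809 and 5775 in co-culture with library size only. In co-culture it was 5461 and 5559 without the filter, 5049 and 5117 without WT co-culture B, 5135 and 5169 without KO co-culture B and 5304 and 5318 without both letter C libraries. The share of higher genes went from 63.8% to 74.4% in WT and from 51% to 41.4% in KO with library size only. With an estimated correlation 0 of 105 list tests passed. Depth limits genes near the floor: Prkcb could not be compared between groups, and folds against a group at 0 are bounds.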

Other observations

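The genes below were chosen after their values were seen, and no test beyond the comparisons named was run on them.

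Hoxc13, a gene of the posterior end of its cluster, stood at 30 CPM in WT monoculture and 29 in WT co-culture, against 0.0181 in KO monoculture and 0 in KO co-culture. Lhx6, a LIM homeobox gene of the jaw and forebrain, stood at 10.1 and 15.5 CPM in WT and 0 in both KO groups. Hand2, a transcription factor of limb, heart and branchial arch, showed the opposite, with 0.022 and 0 CPM in WT and 30.4 and 26.9 in KO.

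H2-Aa, H2-Eb1 and Cd74, which serve MHC class II presentation, fell in KO on co-culture with CLL cells, where the macrophage marker Lyz2 rose (0.81 ± 0.15, adjusted p 0.023). H2-Aa (chromosome 17, 34282744 to 34287823) fell from 25.3 to 8.86 CPM (log2 -1.52, adjusted p 0.00076), H2-Eb1 (chromosome 17, 34305867 to 34316674) from 21.5 to 8.63 CPM (-1.32, adjusted p 0.00199), and the invariant chain Cd74 (chromosome 18, 60803848 to 60812652) from 310 to 193 CPM (-0.68 ± 0.09, adjusted p 0.00199). WT libraries held Cd74 at 2.42 CPM in monoculture and 1.85 in co-culture.

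Some single genes moved in the same direction on co-culture in both genotypes. P4ha1 fell by 0.77 in WT and 1.19 in KO, Loxl2 by 0.57 and 0.50, Loxl4 by 0.48 and 0.93, Egln1, an oxygen sensor that is itself induced in low oxygen, by 0.36 and 0.38, and Vldlr by 0.62 and 1.78 on the log2 scale. Loxl3 rose instead, by 0.50 in KO (adjusted p 0.0423), and by 0.43 in WT without passing (adjusted p 0.0658). Gbp5 (2.52 and 1.80), Phf11b (2.49 and 1.01) and the immunoproteasome subunit Psmb10 (1.09 and 0.81) rose in both.

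Pax5 and Prkcb had more reads in co-culture. The summed level of the 11 tested genes of the B cell list, which do not include Pax5, went from 4.82 to 4.12 CPM in WT. Pax5, the transcription factor of B cell identity, had 4 counts over the WT monocultures, 3 over the KO monocultures, 62 over the WT co-cultures and 11 over the KO co-cultures, and Prkcb had 0, 0, 5 and 10. Tfeb, the transcription factor of lysosome genes, stood at 8.48 ± 0.551 CPM in WT and 18.6 ± 1.14 in KO monoculture (log2 1.13, adjusted p 1.59e-07), with a change of 0.27 on co-culture in each genotype that did not pass (adjusted p 0.199 in WT and 0.133 in KO).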
